A study of Mus musculus with 12 samples.

How the data were processed

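RNA was measured in 12 mouse samples, 11 tumours and 1 skeletal muscle. Per the labels' protocols the tumours were induced genetically, received no drug, and were snap-frozen when the primary tumour had made the animal ill. Libraries were made with a stranded Illumina kit after depletion of ribosomal RNA, also per the labels. The deposited table held whole-number counts per Ensembl gene for 55536 genes, not normalized, with 1 column per sample. The submitters' processing notes name cutadapt, STAR 2.7.5a, featureCounts, RSEM and DESeq2 and the genome build mm10, without a role or an order. The annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here, so overlapping genes, antisense genes, paralogs and pseudogenes may share reads.

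Gene symbols, positions and transcript lengths came from GENCODE M21, on the same build, and 55450 of the 55536 identifiers had a symbol. No column belonged to a sample outside the labels. Groups followed the genotype in the labels, with 5 translocation tumours, 6 Rosa26 tumours and 1 wild-type muscle. Replicate numbers follow the order of the samples and pair nothing. The labels do not say whether each sample came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. All 55 pairs of tumour libraries differed far beyond sampling noise. The smallest median chi-square per gene, between Rosa26 tumours 3 and 6, was 6.43 against 0.455 for sampling noise alone, so no library was counted as a copy of another. This does not show that libraries came from separate animals or tumours.

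Total counts ran from 2.96 to 21.2 M in the translocation tumours and from 6.82 to 21.5 M in the Rosa26 tumours, with 25.0 M in the muscle. A count of 0 over a group was given a floor of 3 counts over that group's libraries, which covers counting error only. Sex was read from Xist and 4 Y-linked genes, since the labels do not give it.

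The genotype comparison used edgeR 4.0.16 in R 4.3.3 on the 11 tumours, with TMM scaling, filterByExpr at its minimum count of 10, robust dispersion and quasi-likelihood tests, and Benjamini-Hochberg adjustment at 0.05. Fold changes are translocation over Rosa26. CPM values are scaled by TMM within the 11 tumours unless the 12-library scale is named. Whole profiles were compared on log2 CPM with a prior count of 2, by the share of variance between genotypes (PERMANOVA, one-sided) and by the difference in mean distance to the group centre (two-sided), each with an exact permutation test over all splits. Gene lists, 27 in number, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry. Tumours were compared with muscle in a fit of all 12 libraries as the mean of both tumour groups minus muscle, with an absolute log2 fold change of at least 1. The spread there came from the tumours alone, and the single muscle library was assumed to vary like them. List medians against muscle were set beside 10000 random lists of the same size matched on expression.

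The genes named were those of the engineered loci, of the FET and CREB families and of sex. To these were added the 10 called genes with the largest rise and the 10 with the largest fall among those whose groups did not overlap, at a mean of at least 5 CPM in the higher group and leaving out clone and model names. Up to 4 members per list were taken by smallest adjusted p. Of the genes so chosen, 2 are not reported here. Against muscle the rule took 8 genes each way at 50 CPM or more with every tumour on the same side of the muscle library, and up to 3 members per list by expression. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

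The lists covered melanocyte and pigment genes, neural crest and Schwann cell genes, cAMP and CREB family targets, immediate early genes, MYC targets of ribosome biogenesis, mitotic genes, replication-dependent histones, p53 targets, amino acid response and ER stress genes, hypoxia and glycolysis genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, interferon and antigen presentation genes, and anterior and posterior Hox genes. Other cell types were covered by skeletal muscle, macrophage, T and NK cell, B and plasma cell, neutrophil, endothelial, fibroblast and collagen, adipocyte, epidermal keratinocyte, erythroid, cartilage and bone, and neuronal lists.

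Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no filter, a filter of 1 CPM in 5 libraries, muscle kept in the fit, the sum of libraries whose titles share a number, covariates for sex, for the skeletal muscle list and for 1 surrogate variable (sva 3.50.0), clone and model names left out, and each tumour left out in turn. For whole profiles a prior count of 0.5, the 1000 most variable genes and the removal of muscle and mitochondrial genes were tried. Alternatives added after the data were seen were the removal of abundant ribosomal and noncoding genes, a covariate for the ribosomal share, an offset for transcript length and GC, and a fit without translocation tumours 2 and 5 and Rosa26 tumour 4.

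The tests were also run on counts simulated from the means, library sizes and dispersions of the real fits. For the genotype comparison, over 3 rounds of 17021 genes with 200 changed, 0.5% of genes changed 2-fold, 32.1% of those changed 4-fold and 65.5% of those changed 8-fold were recovered, and 13 of 204 calls (6.4%) were false. For tumours against muscle, with 22184 genes, 20.4% of 8-fold and 47.9% of 32-fold changes were recovered with 3 false calls. The simulated genes were drawn independently, with the same dispersion in every group and no library set apart. The real tumours differ in these points, so the rates need not hold for them.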

Results

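The series title sets EWSR1-ATF1 expressed from the Rosa26 locus after Cre recombination against a translocation between the mouse Ewsr1 and Atf1 genes. EWSR1-ATF1 is the fusion that drives clear cell sarcoma, a soft tissue tumour with melanocytic features. The translocation tumours (n = 5) arose in mice with Cre from the Hprt locus and loxP sites in both genes, and the Rosa26 tumours (n = 6) in mice with a Cre-activated fusion transgene. Skeletal muscle labelled wild-type was represented by 1 library. Its title shares its leading number with translocation tumour 1, and the labels do not say whether the 2 came from 1 animal. Total counts were 9.01, 2.96, 19.9, 16.6 and 21.2 M in translocation tumours 1 to 5 and 14.6, 12.4, 20.4, 6.82, 21.5 and 16.1 M in Rosa26 tumours 1 to 6. The abundant genes Gm26917, Gm42418 and Gm23935, which hold ribosomal sequence, took 37.8% of counts in translocation tumour 2 and 30% in Rosa26 tumour 4, against 1.34% to 7.38% in the other tumours. Skeletal muscle genes took 11.2% of counts in Rosa26 tumour 1, at most 0.675% in the other tumours and 26.2% in the muscle. Xist and Y-linked genes read as 4 female and 1 male translocation tumours (tumour 5 male) and as 2 female and 4 male Rosa26 tumours.

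The genes at the engineered loci were examined first, since they bear on the labels. Atf1, the CREB family factor that forms the 3' part of the fusion (ENSMUSG00000023027, chromosome 15, 100227819 to 100261244, mm10), was 53.4 ± 15.2 CPM in the translocation tumours (SD, n = 5) and 24.01 ± 2.74 CPM in the Rosa26 tumours (SD, n = 6), without overlap. Ewsr1, the FET family gene that gives the 5' part (ENSMUSG00000009079, chromosome 11, 5069689 to 5099266), was 140 ± 54.4 and 131 ± 20.8 CPM. Gt(ROSA)26Sor, the noncoding transcript of the Rosa26 locus (ENSMUSG00000086429, chromosome 6, 113067428 to 113077333), was 17.3 ± 7.002 CPM in the translocation tumours and 2.63 ± 2.86 CPM in the Rosa26 tumours, again without overlap. Within the Rosa26 tumours it was 0.442 to 1.33 CPM in tumours 1 to 4 and 6.23 and 6.35 CPM in tumours 5 and 6, or 36.0% and 36.7% of the translocation mean. Hprt, which carries the Cre insertion (ENSMUSG00000025630, chromosome X, 52988137 to 53021659), was 19.1 ± 8.70 and 37.7 ± 15.7 CPM, with 5.25 CPM in translocation tumour 5.

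By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Atf1 rose by a log2 fold change of 1.15 ± 0.22 (SE, adjusted p = 0.0274) and kept its call in 7 of 11 leave-one-out fits. The Atf1 call ended without translocation tumour 1 (edgeR adjusted p = 0.0629) and without Rosa26 tumours 3, 5 or 6 (edgeR adjusted p = 0.0884, 0.0582 and 0.077). Gt(ROSA)26Sor had a log2 fold change of 2.71 ± 0.73 and missed the threshold (edgeR adjusted p = 0.0631). Neither Ewsr1 (log2 fold change 0.09, edgeR adjusted p = 0.869) nor Hprt (-0.99, edgeR adjusted p = 0.187) passed. The neighbours of the Rosa26 locus, Thumpd3 and Setd5, had log2 fold changes of 0.95 and -0.08, and the family members Taf15, Creb1 and Crem had -0.27, 0.22 and 0.81, with no call among them. Without translocation tumour 5 Thumpd3 had 0.59, Crem 0.14 and Ewsr1 -0.16, and without translocation tumour 1 Creb1 had -0.12. In the translocation tumours the counts of Atf1 and Ewsr1 cannot separate reads of the normal and the fused allele. Whether reads of the fusion transgene in the Rosa26 tumours were counted under mouse Atf1 or Ewsr1 is not known. The Atf1 values may therefore cover unlike transcripts in the translocation and the Rosa26 tumours. Gt(ROSA)26Sor overlaps the end of Thumpd3 on the other strand. The muscle library held 95.8 CPM of Atf1 and 145 CPM of Ewsr1 on the 12-library scale.

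**Figure D1:**
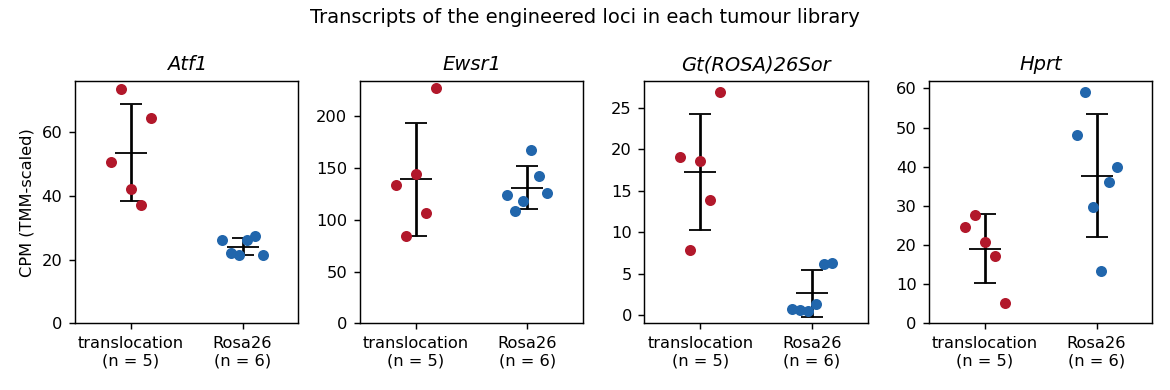
CPM (TMM-scaled) of Atf1, Ewsr1, Gt(ROSA)26Sor and Hprt, with 1 point per tumour library and bars for the mean and SD of 5 translocation and 6 Rosa26 tumours. Atf1 and Gt(ROSA)26Sor do not overlap between the genotypes, while Ewsr1 and Hprt do.

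Whole profiles differed by genotype, and translocation tumour 5 lay apart from all others. The median Spearman's rho was 0.837 over 10 pairs of translocation tumours, 0.903 over 15 pairs of Rosa26 tumours and 0.84 over 30 pairs between genotypes. Without translocation tumour 5 it was 0.886 over 6 pairs of translocation tumours and 0.85 over 24 pairs between genotypes. Genotype held 24.6% of the variance of log2 CPM over 17021 genes (exact permutation p = 0.00216, one-sided, the smallest possible over all splits). The mean distance to the group centre was 161.9 in the translocation tumours (n = 5) and 103.1 in the Rosa26 tumours (n = 6), a difference of 58.8 (exact permutation p = 0.0303, two-sided). Unequal spread can also move the p-value of the share of variance. Both tests treated Rosa26 tumours 5 and 6 as separate samples, and their sum was not tried for whole profiles. Translocation tumour 5 lay farthest from its group's centre at 230.9, followed by translocation tumour 2 at 181.6. The difference in spread no longer passed without translocation tumour 2 (53.9, exact permutation p = 0.0524), translocation tumour 5 (33.3, exact permutation p = 0.129), Rosa26 tumour 3 (51.5), 5 (55.9) or 6 (50.3, exact permutation p = 0.0635 for each of these), or without translocation tumours 2 and 5 and Rosa26 tumour 4 together (24.5, exact permutation p = 0.25).

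**Figure D2:**
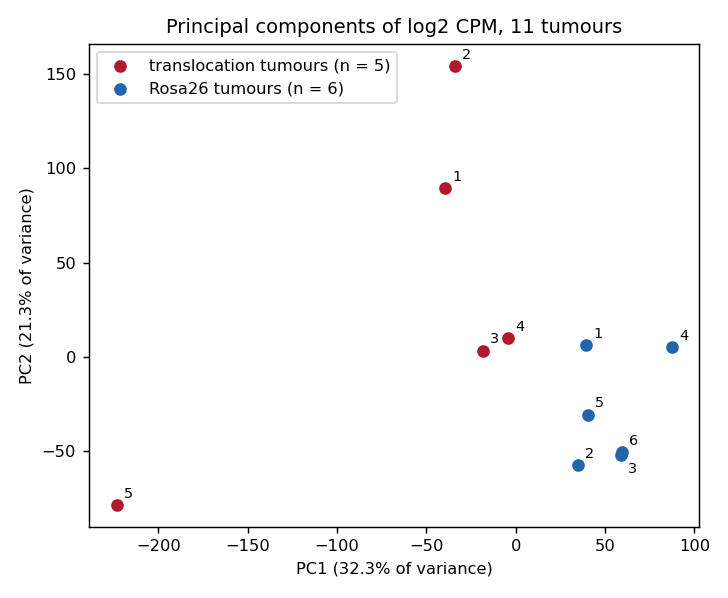
First and second principal components of log2 CPM, in units of the component score, with 1 numbered point per tumour library. Translocation tumour 5 lies at -223 on the first component, which holds 32.3% of the variance, and apart from all other tumours.

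Named genes that rose in the translocation tumours had varied roles. Sertm1, which encodes a small membrane protein, reached 58.1 ± 79.1 CPM (SD, n = 5) against 0.428 ± 0.370 CPM in the Rosa26 tumours (SD, n = 6), a log2 fold change of 6.96 ± 1.09 (SE, edgeR adjusted p = 0.0118). Gchfr, the feedback regulator of GTP cyclohydrolase, rose by 6.77 ± 1.19 on the log2 scale (SE, edgeR adjusted p = 0.0181), Lrrtm3, a synaptic adhesion protein gene, by 4.41 and Col24a1, a fibrillar collagen gene, by 4.26. Tnfrsf9, a costimulatory receptor of lymphocytes, was 158 ± 102 against 11.1 ± 7.53 CPM (log2 fold change 3.83, edgeR adjusted p = 0.0141), and the platelet chemokine Pf4 was 74.6 ± 80.6 against 5.46 ± 2.06 CPM (3.76, edgeR adjusted p = 0.0181). Clec4d, a lectin gene of myeloid cells, rose by 3.97, Efcab6 by 3.31, Cox6b2, the testis form of a cytochrome c oxidase subunit, by 3.28, and Mpped1 by 2.69 on the log2 scale. The calls of Gchfr, Pf4 and Efcab6 ended without Rosa26 tumour 3 or 6 (edgeR adjusted p = 0.0594 to 0.0647), and those of Lrrtm3 and Cox6b2 without Rosa26 tumour 3 (0.0519 and 0.0528). The Col24a1 call held only without translocation tumours 2, 3 or 4 or Rosa26 tumour 4. The Clec4d call held only without translocation tumours 2, 3, 4 or 5 (edgeR adjusted p up to 0.122 in the other fits). Without translocation tumour 5 the log2 fold changes of Gchfr and Col24a1 were 4.45 and 2.51. Without translocation tumour 1 those of Clec4d and Pf4 were 2.29 and 2.87, and without translocation tumour 3 those of Sertm1 and Cox6b2 were 5.70 and 2.47. Lrrtm3 had 5.22 without Rosa26 tumour 6. Sertm1 lies on chromosome 3 at 54897068 to 54915887, Tnfrsf9 on chromosome 4 at 150914562 to 150946102 and Mpped1 on chromosome 15 at 83779467 to 83858494.

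Among the named genes that fell, several had almost no counts in any translocation tumour. Nps, which encodes the precursor of neuropeptide S (chromosome 7, 135258703 to 135272942), was 205 ± 184 CPM in the Rosa26 tumours (SD, n = 6) and held 3 counts in all 5 translocation libraries, against 22592 in the Rosa26 libraries (edgeR adjusted p = 0.00826). Vwde (chromosome 6, 13156299 to 13224965) was 95.8 ± 70.2 CPM in the Rosa26 tumours against 2 counts in the translocation tumours (edgeR adjusted p = 0.00662). Slc17a6, a vesicular glutamate transporter gene, Esrp1, an epithelial splicing regulator, and Cib4 had 0 counts in the translocation tumours and were at least 529-fold, 230-fold and 184-fold lower than in the Rosa26 tumours, against the floor of 3 counts over the group. The Wnt antagonist gene Sfrp5 was 231 ± 177 CPM in the Rosa26 tumours and 0.672 ± 1.04 CPM in the translocation tumours (log2 fold change -9.28, edgeR adjusted p = 0.0132). The tryptase gene Tpsg1 and the glucuronyltransferase gene B3gat2 held 2 and 3 counts in the translocation tumours. Tdo2, which encodes tryptophan dioxygenase, and F2rl1, a protease-activated receptor gene, fell by 7.95 and by 7.25 on the log2 scale. The Slc17a6 call ended without translocation tumour 1 or Rosa26 tumours 3, 5 or 6 (edgeR adjusted p = 0.0559, 0.0784, 0.0587 and 0.0658) and the Esrp1 call without translocation tumour 1 (0.0551). Without any 1 of Rosa26 tumours 1, 2, 3, 5 and 6 the filter removed Esrp1 and B3gat2.

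Over all 17021 genes tested, 460 passed the edgeR test, 194 higher and 266 lower in the translocation tumours, and 352 of them had groups that did not overlap. In all, 881 tested genes (5.18%) had groups that did not overlap, where chance gives 0.433%. Rosa26 tumours 5 and 6 have titles that differ only in the last digit and may come from 1 animal. Summed as 1 sample they left 91 calls, 26 higher and 65 lower. The counts rested on single libraries, with 112 calls without translocation tumour 1, 744 without translocation tumour 5, and 63, 262, 123 and 75 without Rosa26 tumours 3, 4, 5 and 6, while leaving out Rosa26 tumour 1 lowered the higher calls to 121. With sex as a covariate 2534 genes passed and with the skeletal muscle list as a covariate 292. Without translocation tumours 2 and 5 and Rosa26 tumour 4 the count was 619, of which 258 were among the 460. Sertm1, Tnfrsf9, Mpped1, Nps, Vwde, Cib4, Sfrp5, Tpsg1, Tdo2 and F2rl1 were called in all 11 leave-one-out fits. Of the 40 named genes that passed, leaving out Rosa26 tumours 3, 6 or 5 or translocation tumour 1 ended 25, 23, 19 and 20 calls, and any other tumour 3 to 11.

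**Figure D3:**
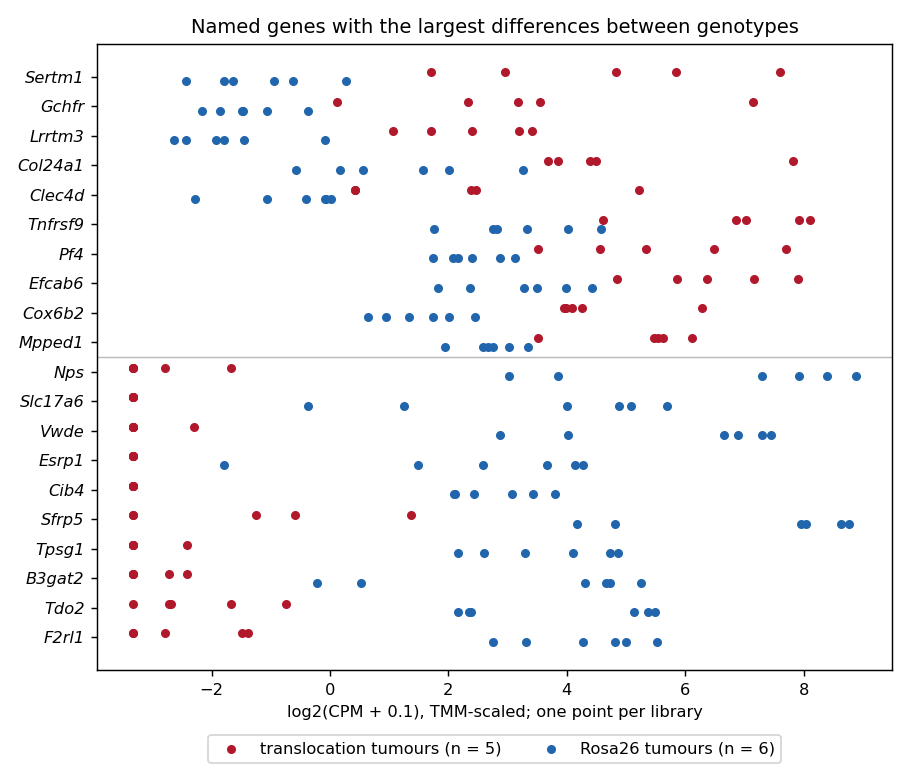
Log2 of CPM (TMM-scaled) plus 0.1 for the 10 named genes with the largest rise, above the line, and the 10 with the largest fall, below it, with 1 point per library of 5 translocation and 6 Rosa26 tumours. For each gene the groups do not overlap, and Slc17a6, Esrp1 and Cib4 sit at 0 counts in all translocation tumours.

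Few lineage genes passed singly, and in the main fit neither the melanocyte nor the neural crest list passed camera. For a shift in 1 direction fry gave adjusted p = 0.0945 for the melanocyte and 0.109 for the neural crest list. For changes in either direction fry gave adjusted p = 0.00211 and 7.38e-06. Such a pass was not particular to these lists, since hypoxia genes (fry adjusted p = 0.00581), p53 targets (0.00857) and others passed too. For a shift in 1 direction no list passed fry, nuclear oxidative phosphorylation genes included (fry adjusted p = 0.0817). Rab27a, which moves melanosomes, fell by 2.04 on the log2 scale (edgeR adjusted p = 0.0321), and Bcl2, a survival gene under the melanocyte regulator Mitf, fell by 2.44 (edgeR adjusted p = 0.0363), while Gpnmb had 4.36 without a call (edgeR adjusted p = 0.084) and 0.95 without translocation tumour 5. The Rab27a call ended without translocation tumours 1 or 4 or Rosa26 tumours 3, 5 or 6 (edgeR adjusted p = 0.0518 to 0.0908), and the Bcl2 call held only without translocation tumours 2, 4 or 5 or Rosa26 tumour 2 (0.053 to 0.0968 in the other fits). Of 13 tested melanocyte and pigment genes, 0 rose and 2 fell, or 1 and 2 adjusted over the list alone. The list's median was 0.09 while camera pointed down, and it did not pass (camera adjusted p = 0.104, and 0.442 with an estimated correlation). Without translocation tumour 5 the median was -1.05 and the list passed as lower (camera adjusted p = 0.0257). The pigment genes Tyr and Tyrp1 held 3 and 2 counts over all 11 tumours and Mlana held 0, and Sox10 held 31 counts in 6 libraries, so the filter left them out. The highest value in any tumour was 0.495 CPM for Tyr, 0.0442 CPM for Tyrp1 and 1.98 CPM for Sox10. These transcripts were thus scarce in both genotypes. Gap43, a growth cone protein of neural crest derivatives, fell by 5.59 ± 0.85 on the log2 scale (SE, edgeR adjusted p = 0.0116), from 26.8 ± 13.2 to 0.534 ± 0.851 CPM (-7.08 without translocation tumour 1), while S100b had 1.44 (edgeR adjusted p = 0.0624). Of 14 neural crest and Schwann cell genes 0 rose and 1 fell, or 1 and 1 adjusted over the list alone. The median was 0.21, the mean -0.01 and the camera adjusted p = 0.577. That median turned to -0.16 without translocation tumour 5 and to -0.22 without translocation tumours 2 and 5 and Rosa26 tumour 4.

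Neuronal genes had mostly negative fold changes. Map2 and Snap25 had log2 fold changes of -1.93 and -3.01 (edgeR adjusted p = 0.0549 and 0.0718), and 11 of 13 members were negative. Of the 13, 0 passed over all genes and 4 were lower adjusted over the list alone. The median was -1.68 and the list passed camera (adjusted p = 0.00214), with adjusted p = 0.442 with an estimated correlation. The call ended with sex as a covariate (median -0.97, camera adjusted p = 0.0993). Among posterior Hox genes, which pattern the hind body and limbs, Hoxc11 fell by 4.96 ± 0.85 on the log2 scale (SE, edgeR adjusted p = 0.0171), and Hoxa10 and Hoxc10 had -1.14 and -0.84. Of the list's 16 members 6 were tested. All 6 were negative, 0 rose and 1 fell, also adjusted over the list alone. The median was -0.95 (camera adjusted p = 0.00408, and adjusted p = 0.442 with an estimated correlation). The filter left out the other members. Among these Hoxd13 went the other way, at 57.5 CPM in translocation tumour 5 and at most 0.448 CPM in the Rosa26 tumours. The list mean was -2.96 and -1.20 log2 CPM in translocation tumours 3 and 5 and 3.13 in translocation tumour 4, within the Rosa26 range of 3.12 to 4.15, and without tumour 3 the median was -0.62 (camera adjusted p = 0.0134). Hoxc11 had -6.17 without translocation tumour 4. Of 9 anterior Hox genes 0 passed, also adjusted over the list alone, with Hoxb3 at 2.02 and Hoxb4 at 1.78. Their median was 0.03 while camera pointed down (camera adjusted p = 0.723).

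Among targets of the cAMP and CREB pathway, to which Atf1 belongs, 2 genes fell. Nr4a3, an orphan nuclear receptor gene, fell by 3.39 ± 0.74 on the log2 scale (SE, edgeR adjusted p = 0.0379), from 309 ± 141 CPM in the Rosa26 tumours (SD, n = 6) to 29.2 ± 31.8 CPM (SD, n = 5). Pcsk1, a prohormone convertase gene, fell by 3.88 (edgeR adjusted p = 0.0492), from 733 ± 567.6 to 49.6 ± 51.7 CPM. The Nr4a3 call held only without translocation tumour 5 or Rosa26 tumour 1, and the Pcsk1 call only without translocation tumour 3 or Rosa26 tumours 1 or 4 (edgeR adjusted p = 0.0518 to 0.119 in the other fits). Nr4a3 had -4.27 without translocation tumour 5 and Pcsk1 -4.73 without translocation tumour 3. Of 23 targets 0 rose and 2 fell, or 0 and 5 adjusted over the list alone, with a median of -0.49 (camera adjusted p = 0.0107, and adjusted p = 0.442 with an estimated correlation). The list no longer passed without translocation tumours 2 and 5 and Rosa26 tumour 4 (median -0.19, camera adjusted p = 0.0724). Among immediate early genes, the zinc finger gene Klf6 rose by 1.27 (edgeR adjusted p = 0.0134) and Klf4 fell by 1.68 on the log2 scale (edgeR adjusted p = 0.0447). The Klf6 call ended without Rosa26 tumours 3 or 6 (edgeR adjusted p = 0.0528 and 0.0563), and the Klf4 call held only without translocation tumour 5 or Rosa26 tumour 1 (0.0541 to 0.121 in the other fits). Of 22 members 1 rose and 1 fell, or 1 and 3 adjusted over the list alone, with a median of -0.47 (camera adjusted p = 0.0372, and adjusted p = 0.611 with an estimated correlation). That call ended without translocation tumour 4 (camera adjusted p = 0.0786), translocation tumour 5 (0.17) or Rosa26 tumour 4 (0.138).

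Growth genes were raised in 1 tumour in particular. Odc1, the first enzyme of polyamine synthesis, rose by 1.40 (edgeR adjusted p = 0.0356), the 1 call higher among 28 MYC targets of ribosome biogenesis, with 0 lower and the same counts adjusted over the list alone (median 0.65, camera adjusted p = 0.0853). The Odc1 call ended without translocation tumour 3 or any 1 of Rosa26 tumours 1, 3, 4, 5 and 6 (edgeR adjusted p = 0.0537 to 0.101). The list passed as higher without translocation tumours 1, 2, 3 or 4 (camera adjusted p = 0.0228, 0.043, 0.0281 and 0.0192). Without translocation tumour 5 its median was -0.23 and camera pointed down (camera adjusted p = 0.225). Of 28 mitotic genes 0 passed, also adjusted over the list alone. Of the 28, 27 were positive, such as Ccnb1 at 2.82 and Cdk1 at 2.28 (edgeR adjusted p = 0.102 and 0.103), with a median of 1.25 (camera adjusted p = 0.0984). The mitotic list had a mean log2 CPM of 7.04 in translocation tumour 5 and 3.24 to 4.20 in the other translocation tumours. Without tumour 5 its median was -0.27 and it passed as lower (camera adjusted p = 0.0397), and without translocation tumours 1, 2 or 4 it passed as higher (camera adjusted p = 0.00305, 0.0319 and 0.0283). Of 22 replication-dependent histone genes 0 passed over all genes and 15 were higher adjusted over the list alone, with Hist1h4c at 2.09 and a median of 2.01 (camera adjusted p = 0.00575, and adjusted p = 0.698 with an estimated correlation). Without tumour 5 the histone median was 0.29 and the call ended (camera adjusted p = 0.613). It also ended with the offset for transcript length and GC (1.39, camera adjusted p = 0.175) and without translocation tumours 2 and 5 and Rosa26 tumour 4 (-0.02, camera adjusted p = 0.88). With sex as a covariate the MYC target and mitotic lists passed as higher (camera adjusted p = 0.000138 and 0.000717).

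Of 15 p53 targets 0 rose and Zmat3 fell by 1.36 on the log2 scale (edgeR adjusted p = 0.0285), a call that ended without translocation tumours 1 or 4 or Rosa26 tumours 3, 5 or 6 (0.0508 to 0.0901). Adjusted over the list alone 0 were higher and 2 lower, Pmaip1 at -1.75 among them. The median was 0.01 while camera pointed down (camera adjusted p = 0.46). Of 18 amino acid response and ER stress genes 0 passed, also adjusted over the list alone, with Sdf2l1 at 1.16 and Atf4 at 0.70 and a median of 0.60 (camera adjusted p = 0.0818). That list passed as higher without translocation tumour 3 (camera adjusted p = 0.0153), without Rosa26 tumour 2 (0.0254) or with sex as a covariate (0.0107). Its median was 0.24 without translocation tumour 5 (camera adjusted p = 0.225). Without translocation tumours 2 and 5 and Rosa26 tumour 4 it was 0.03 (camera adjusted p = 0.949).

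The 24 nuclear oxidative phosphorylation genes tested had positive fold changes, of which 2 passed singly. Cox4i1, a subunit of cytochrome c oxidase, rose by 1.75 ± 0.35 on the log2 scale (SE, edgeR adjusted p = 0.0282), from 203 ± 76.3 CPM (SD, n = 6) to 683 ± 248 CPM (SD, n = 5). Cyc1, the cytochrome subunit of complex III, rose by 1.85 (edgeR adjusted p = 0.0466), and Cox6c and Ndufb8 had 1.69 and 1.68 (edgeR adjusted p = 0.0505 and 0.0516). Of the 24 genes, 2 rose and 0 fell over all genes tested, and 20 were higher adjusted over the list alone. The median was 1.12 (camera adjusted p = 1.49e-10, and adjusted p = 0.442 with an estimated correlation). Translocation tumour 5 had the highest list mean, at 8.58 against 6.88 to 7.28 log2 CPM in the other translocation tumours and 5.22 to 6.91 in the Rosa26 tumours. Without tumour 5 the median was 0.68 with 23 of 24 positive (camera adjusted p = 4.7e-08), and without translocation tumours 2 and 5 and Rosa26 tumour 4 it was 0.62 (camera adjusted p = 2.1e-07). The Cox4i1 call ended in that last fit (edgeR adjusted p = 0.0683), and also without translocation tumour 1 or Rosa26 tumours 3, 5 or 6 (0.0658, 0.0901, 0.0714 and 0.077). The Cyc1 call held only without translocation tumours 2, 4 or 5 (edgeR adjusted p = 0.0511 to 0.125 in the other fits), with a log2 fold change of 1.13 without tumour 5.

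Of 10 mitochondrially encoded genes 0 passed, also adjusted over the list alone, with mt-Nd6 at 1.27 and mt-Co1 at 0.55. Their median was 0.42 (camera adjusted p = 0.0372, and adjusted p = 0.698 with an estimated correlation). That call ended without translocation tumours 1, 3 or 5 (camera adjusted p = 0.0732, 0.0517 and 0.11) or Rosa26 tumours 4 or 6 (0.176 and 0.12), and without Rosa26 tumour 1 the median was 1.05. Among hypoxia genes, Ddit4, an inhibitor of mTOR signalling, rose by 2.42 ± 0.46 (SE, edgeR adjusted p = 0.0237), from 29.0 ± 15.5 to 155 ± 97.6 CPM, and Ndrg1 rose by 1.37 (edgeR adjusted p = 0.0429). The Ddit4 call ended without translocation tumour 1 or Rosa26 tumours 3, 5 or 6 (edgeR adjusted p = 0.0551 to 0.0795), and the Ndrg1 call held only without translocation tumours 2, 4 or 5 or Rosa26 tumour 2 (0.0503 to 0.123 in the other fits). Of 20 hypoxia and glycolysis genes 15 were positive and 5 negative, 2 rose and 0 fell, or 4 and 0 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 0.0026, and adjusted p = 0.442 with an estimated correlation). Without Rosa26 tumour 2 the median was 1.10, and without translocation tumours 2 and 5 and Rosa26 tumour 4 the list no longer passed (camera adjusted p = 0.0914).

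Among the listed markers of blood and immune cells 1 gene passed, Cd3e. Of 8 erythroid genes 0 passed over all genes and 6 were higher adjusted over the list alone, with Slc4a1, the red cell anion exchanger, at 6.52 and Hbb-bt at 4.75 (edgeR adjusted p = 0.0579 and 0.115). The erythroid median was 3.74 (camera adjusted p = 0.00169, and adjusted p = 0.442 with an estimated correlation), and translocation tumour 1 had a list mean of 8.36 log2 CPM against 3.02 to 4.09 in the other translocation tumours. Without that tumour the erythroid median was 0.68 (camera adjusted p = 0.00305), and without Rosa26 tumour 1 it was 5.75. The T cell receptor subunit gene Cd3e fell by 4.93 on the log2 scale (edgeR adjusted p = 0.0413), a call that held only without Rosa26 tumour 2 where it was tested (0.0537 to 0.0852 in the other fits), while Cd8a had -3.99 and the granzyme gene Gzma 4.13 (edgeR adjusted p = 0.0557 and 0.0561). Of 15 T and NK cell genes 0 rose and 1 fell, or 1 and 5 adjusted over the list alone, with a median of -1.18 (camera adjusted p = 0.0465, and adjusted p = 0.698 with an estimated correlation). That call ended without translocation tumours 3 or 5 (camera adjusted p = 0.0882 and 0.225) or any 1 of Rosa26 tumours 1, 3, 4, 5 and 6 (0.124 to 0.407). Over all alternatives the median of the T and NK cell list ran from -1.72 to -0.49. Of 6 neutrophil genes 0 passed and 1, Mmp9 at 4.38, was higher adjusted over the list alone, with a median of 2.47 (camera adjusted p = 0.0372, and adjusted p = 0.513 with an estimated correlation). The neutrophil call ended without translocation tumours 1 or 2 (camera adjusted p = 0.106 and 0.128) or any 1 of Rosa26 tumours 2 to 6 (0.0538 to 0.0939).

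Of 17 macrophage genes 0 passed, also adjusted over the list alone, with Tyrobp at 1.40 and a median of 0.42 (camera adjusted p = 0.152). The list passed as higher without translocation tumour 5 (camera adjusted p = 0.0217) or Rosa26 tumour 5 (0.0362). Its median ran from 0.03 to 0.74 over all alternatives. Of 5 B and plasma cell genes 0 passed, also adjusted over the list alone, with Cd22 at -2.03, a median of 0.82 and a mean of -0.13 while camera pointed down (camera adjusted p = 0.837), and a median of -1.36 without translocation tumour 2. Of 22 interferon and antigen presentation genes 0 passed, also adjusted over the list alone, with Oasl2 at -1.66 and a median of -0.55 (camera adjusted p = 0.0152, and adjusted p = 0.698 with an estimated correlation). The interferon call ended without translocation tumour 5 (median -0.28, camera adjusted p = 0.225) or Rosa26 tumour 4 (0.0932).

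Vessel, stroma and epithelial lists had mostly negative fold changes. The endothelial transcription factor gene Erg fell by 2.93 on the log2 scale (edgeR adjusted p = 0.0367) while Egfl7, a secreted endothelial factor gene, rose by 2.50 (edgeR adjusted p = 0.0431). The Erg call held only without translocation tumours 4 or 5 or Rosa26 tumours 1 or 2, and the Egfl7 call only without translocation tumour 5 (edgeR adjusted p = 0.053 to 0.123 in the other fits), and without translocation tumour 4 Erg had -3.54. Of 14 endothelial genes 1 rose and 1 fell, or 2 and 6 adjusted over the list alone, with a median of -1.16 (camera adjusted p = 0.00169, and adjusted p = 0.442 with an estimated correlation). Without translocation tumours 2 and 5 and Rosa26 tumour 4 that list did not pass (camera adjusted p = 0.0689). Sfn, an epithelial adaptor protein gene, fell by 3.01 on the log2 scale (edgeR adjusted p = 0.0466), a call that held only without translocation tumour 5 or Rosa26 tumour 1 among the leave-one-out fits (0.0502 to 0.122 in the others), and the desmosomal cadherin gene Dsg3 had -5.86 (edgeR adjusted p = 0.0608). Of 18 epidermal keratinocyte genes 7 were tested. The filter left out the rest, Krt5, Krt1, Ivl, Lor and Flg among them, so the list values do not cover these keratinocyte genes. Of the 7 tested, 0 rose and 1 fell, or 0 and 4 adjusted over the list alone. Their median was -1.56 (camera adjusted p = 0.0026, and adjusted p = 0.442 with an estimated correlation) and -2.96 without translocation tumour 4. Of 22 fibroblast and collagen genes 0 passed, also adjusted over the list alone, with Col1a1 at -2.73 and a median of -0.62 (camera adjusted p = 0.0372, and adjusted p = 0.707 with an estimated correlation). That call ended without translocation tumour 5 (median -0.43, camera adjusted p = 0.645) or Rosa26 tumours 3, 4 or 6 (0.0701, 0.138 and 0.0546), and the median was -1.24 without translocation tumour 4.

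In the cartilage and bone list Spp1, which encodes osteopontin, rose by 2.82 (edgeR adjusted p = 0.0491, held only without translocation tumours 2 or 5 or Rosa26 tumour 1, and 0.0565 to 0.129 in the other fits, with 2.04 without translocation tumour 3), while Sox9 and Acan had -2.05 and -4.80. Of its 10 genes 1 rose and 0 fell, or 1 and 3 adjusted over the list alone (median 0.00, camera adjusted p = 0.117); the list passed as lower without translocation tumour 3 (camera adjusted p = 0.0332) or Rosa26 tumour 5 (0.0466). Of 7 adipocyte genes 0 passed, also adjusted over the list alone, with Lpl at -1.57 and a median of -0.78 (camera adjusted p = 0.577), which was 0.67 without Rosa26 tumour 1. Of 21 skeletal muscle genes 0 passed, also adjusted over the list alone, with Eno3 at -1.74 and 21 of 21 negative at a median of -2.81 (camera adjusted p = 0.577). That median rested on Rosa26 tumour 1, without which it was 0.98 and camera pointed up (camera adjusted p = 0.402). Without translocation tumour 2 it was -6.86 and the list passed as lower (camera adjusted p = 0.0439). It also passed as lower without translocation tumours 2 and 5 and Rosa26 tumour 4 (camera adjusted p = 0.0215).

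In the main fit no list's call held with an estimated correlation, which was not tried in the alternatives. Of the 16 alternatives other than leaving out 1 tumour, 8 ended the call of the neutrophil list (camera adjusted p = 0.0605 to 0.297) and 6 that of the T and NK cell list (0.0525 to 0.288). The mitochondrially encoded list lost its call in 5 (0.0683 to 0.23), the fibroblast and collagen list in 4 (0.0657 to 0.573) and the immediate early list in 3 (0.0562 to 0.35). The interferon call ended in 1, the fit without translocation tumours 2 and 5 and Rosa26 tumour 4 (camera adjusted p = 0.307).

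**Figure D4:**
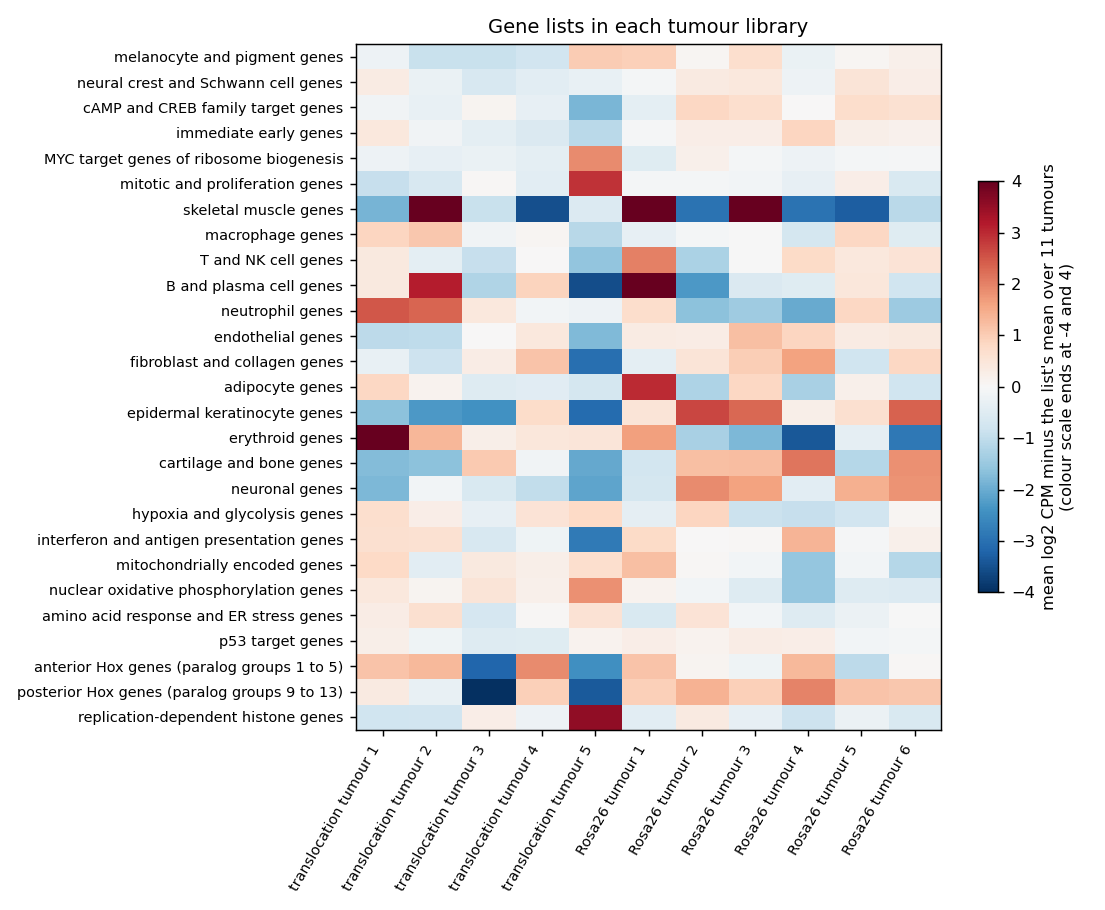
Mean log2 CPM of the members of each of 27 gene lists in each of the 11 tumour libraries, minus the list's mean over the tumours, on a colour scale that ends at -4 and 4. The list mean of nuclear oxidative phosphorylation genes is 6.88 to 8.58 in the translocation and 5.22 to 6.91 in the Rosa26 tumours, and translocation tumour 5 stands apart in the mitotic, histone and MYC target lists.

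Against the muscle library, the tumours held fewer skeletal muscle transcripts and more matrix, cell cycle, macrophage, T and NK cell and neuronal transcripts. Rosa26 tumour 1, with 11.2% of its counts in skeletal muscle genes, came nearest to the muscle's 26.2%. The genes with the largest excess had 0 counts in the muscle library: the link protein gene Hapln1, the vesicle gene Rab3c, the cartilage proteoglycan gene Acan and the fibrillin gene Fbn2 were at least 1872-fold, 1533-fold, 1248-fold and 617.5-fold higher over the mean of the 11 tumours, against a floor of 3 counts in the muscle. Tmprss6, Sez6l2, Dsg2 and Fam167a followed at 426-fold, 425.7-fold, 348-fold and 218-fold or more. These means pool both genotypes and need not describe each one. Acan, for example, had log2 fold changes of -7.06 to -3.61 for translocation over Rosa26 tumours across the alternatives. The lowest were Ucp3, a mitochondrial uncoupling protein gene, and the sarcomere genes Myoz2 and Csrp3, with log2 fold changes of -10.67 ± 2.28, -10.17 ± 1.59 and -10.12 ± 1.54 (SE), then Odf3l2 (-9.72), Ankrd2 (-9.67), Abra (-9.57), Trim63 (-9.36) and Sln (-9.18). The mitotic list had a median of 3.53, the macrophage list 3.39, the fibroblast and collagen list 3.94 and the cartilage and bone list 7.03, at the 100, 99.98, 100 and 100 percentiles of random lists. The skeletal muscle, mitochondrially encoded and nuclear oxidative phosphorylation lists had medians of -6.70, -3.65 and -2.41, at the 0, 0.02 and 0 percentiles. The T and NK cell and neuronal lists had medians of 6.7 and 5.8, both at the 100 percentile. Other low lists included erythroid genes (-2.24), p53 targets (-1.49) and posterior Hox genes (-1.34), at the 0.16, 0.24 and 0.1 percentiles. The neutrophil list had -0.42, at the 3.21 percentile, and the melanocyte and pigment list 0.17, at the 24.7 percentile.

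With an absolute log2 fold change of at least 1, 3686 of 22184 genes passed the edgeR test, 1165 higher and 2521 lower in the tumours. Of the genes named above for their excess, Hapln1, Acan, Tmprss6 and Dsg2 did not pass (edgeR adjusted p = 0.142, 0.127, 0.0774 and 0.122), while Rab3c, Fbn2, Sez6l2 and Fam167a did (edgeR adjusted p = 0.0474, 0.0297, 0.0452 and 0.034). The single muscle library was assumed to vary like the tumours, so the test compares these tumours with that library. The count was 5987 without translocation tumour 5, 7037 without translocation tumours 2 and 5 and Rosa26 tumour 4, and 5558 by DESeq2; lower genes made up 68.4% of the calls, against 58.0%, 56.4% and 46.4% in those fits.

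**Figure D5:**
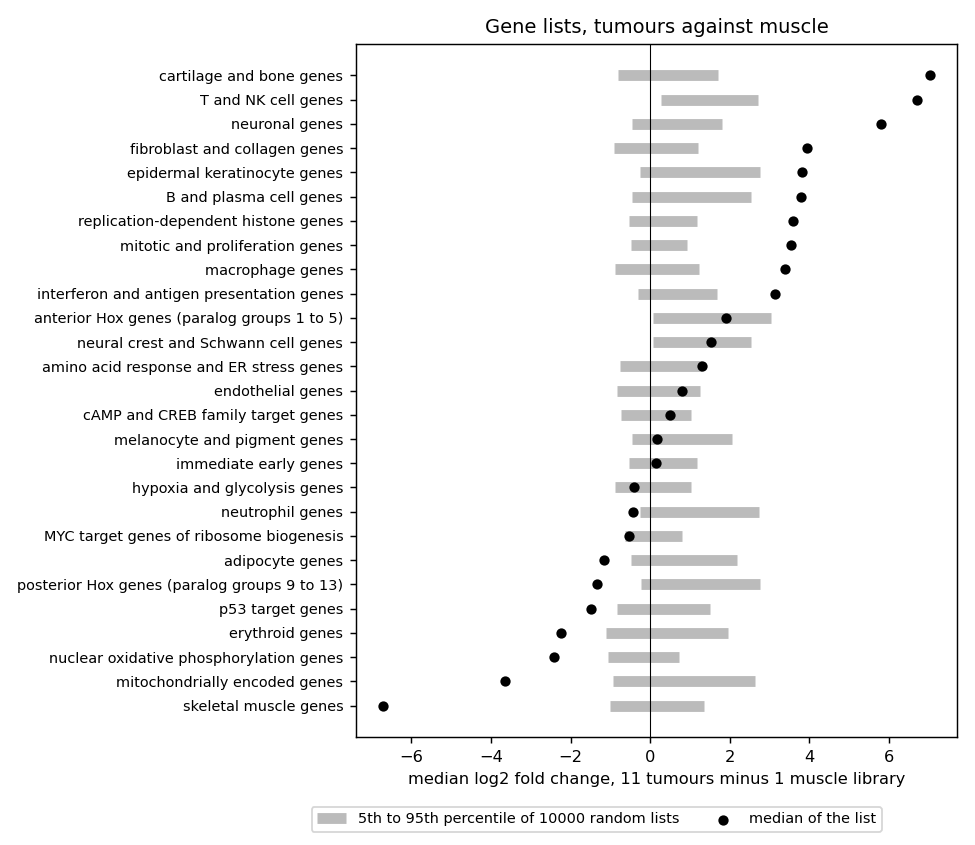
Median log2 fold change of each gene list between 11 tumours and 1 muscle library (points), with the 5th to 95th percentile of 10000 random lists of the same size and expression (grey bars). Cartilage and bone genes lie highest at 7.03 and skeletal muscle genes lowest at -6.70.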

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

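The fits without tumour 5 and with covariates for sex and for the muscle list were set before the values were seen. Their use against the explanations in this part, and the tests of transcript length and GC, of a swapped label, of sex within the Rosa26 tumours and of depth, were chosen only after the result was seen.

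Split at random into 5 and 6, the 11 tumours gave at most 1 called gene in any other of 100 splits, against 460 for the genotypes. Counting the real one, 1 of the 100 splits had as many, so a random grouping of these libraries rarely gave so many calls. The other splits mix the genotypes, which widens the spread within their groups. They therefore do not measure how many of the 460 are false. They also treat Rosa26 tumours 5 and 6 as separate samples.

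The 24 positive fold changes among 24 nuclear oxidative phosphorylation genes, Cox4i1 and Cyc1 among them, stood out as a set. In the main fit the list did not pass with an estimated correlation (camera adjusted p = 0.442). The correlation was not estimated in the other fits, so each camera value below rests on the preset correlation. With an offset for transcript length and GC the median was 0.86 in place of 1.12, and 95.8% of members stayed positive (camera adjusted p = 1.84e-08), so that bias could hold part of the size but not the whole. Without translocation tumour 5 the median was 0.68 (camera adjusted p = 4.7e-08), which speaks against that library as the whole cause. The skeletal muscle list's median was -2.81 but 0.98 without Rosa26 tumour 1, which decides nothing, while with that list as a covariate the oxidative phosphorylation median was 1.16 (camera adjusted p = 1.13e-10), which speaks against muscle tissue as the whole cause. With sex as a covariate the median was 1.31 (camera adjusted p = 2.56e-10). Translocation tumour 5 was the only male translocation tumour, and Rosa26 tumours 1 and 4 were the only female Rosa26 tumours. That fit cannot tell sex from these libraries and does not decide on it. Sex and genotype stay open.

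Translocation tumour 5 stood apart, with mitotic genes 3.37 above the mean of the other 4 on the log2 scale, histones 3.94 above and interferon genes 2.93 below. Its mean for the fibroblast and collagen list, at 4.6 log2 CPM, was the lowest of all 11 tumours. The same held for the B and plasma cell (-0.77), T and NK cell (-0.88), macrophage (4.76) and endothelial (2.93) lists. Its neutrophil mean, at 1, lay within the Rosa26 range of -0.83 to 2.02. Whether this sample held fewer cells of other types was not tested. Translocation tumour 5 may have carried the label of a Rosa26 tumour. However, its Gt(ROSA)26Sor was 26.9 CPM, where the highest Rosa26 tumour had 6.35, and its Atf1 was 64.4 CPM, where the highest had 27.3. Male minus female Rosa26 tumours differed by 0.06 in the mitotic list (SD 0.29 among the Rosa26 tumours) and by -1.01 in the interferon list (SD 0.56). The female side was only Rosa26 tumour 1, with 11.2% of counts in skeletal muscle genes, and Rosa26 tumour 4, with 30% in Gm26917, Gm42418 and Gm23935. The mitotic value speaks against sex only as far as these few libraries go. Sex stays open for the interferon genes. Depth does not set it apart either, at 21.2 M counts. A different kind of tumour or a second lesion stays untested.

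Of 329 groups of values examined with Dixon's test, 35 had a library standing apart, where about 16.4 were to be had by chance at 1 in 20, and 18 of the 35 were in translocation tumour 5. Genes with at most 3 counts over a group were left out by a rule added after the values were seen.

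Translocation tumour 5 was apart in the cAMP and CREB target list (Dixon ratio 0.763), the MYC target list (0.92), the mitotic list (0.748), the nuclear oxidative phosphorylation list (0.766) and the histone list (0.756). It was also apart in Hprt (0.712), Thumpd3 (0.784), Col24a1 (0.804), Bdnf (0.892), Klf4 (0.764), Dctpp1 (0.757) and Ccnb1 (0.839). Further genes were Fap (0.843), Pgk1 (0.891), Oasl2 (0.744), Ndufb8 (0.758), Hist1h4c (0.74) and Hist1h4h (0.716).

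Translocation tumour 1 was apart in the erythroid list (0.8), at 8.36 log2 CPM. Translocation tumour 2 was apart in Tnnt3 (0.857), Ndrg1 (0.791), the share of Gm26917, Gm42418 and Gm23935 (0.834) and the share of skeletal muscle genes (0.87). Translocation tumour 3 was apart in Cox6b2 (0.872), and translocation tumour 4 in Mpped1 (0.757), S100b (0.807) and Dsp (0.772). Rosa26 tumour 1 was apart in Cd22 (0.628), the share of skeletal muscle genes (0.941) and the share of the mitochondrial ribosomal RNAs (0.667). Rosa26 tumour 4 was apart in the immediate early list (0.653), Ms4a7 (0.648) and the share of Gm26917, Gm42418 and Gm23935 (0.811). Rosa26 tumour 5 was apart in Hoxa3 (0.667), and Rosa26 tumour 6 in Lyz2 (0.757).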

How the results depend on the processing

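The genotype calls were compared under the alternatives named with the methods. The DESeq2 Wald test called 2439 genes, 1236 higher and 1203 lower in the translocation tumours, and limma voom 2651, 1252 higher and 1399 lower. Without a filter 92 genes were higher. Sex as a covariate gave 2534 genes, 1551 higher and 983 lower, the skeletal muscle list as a covariate 292 with 98 higher, and 1 surrogate variable 1627, 796 higher and 831 lower. Translocation tumours 2 and 5, whose titles share a number, read as 1 female and 1 male; summing them gave 815 genes, 412 higher and 403 lower, and summing Rosa26 tumours 5 and 6 gave 91, 26 higher and 65 lower. The offset for transcript length and GC gave 288 genes, 125 higher and 163 lower, and with muscle kept in the fit 115 genes were higher.

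Leaving out 1 tumour gave 63 genes (Rosa26 tumour 3) to 744 (translocation tumour 5), 15 to 293 of them higher and 48 to 451 lower. Every call of the main comparison that was tested kept its direction in all these fits, which share most of their libraries with the main one. Of the 460 calls, 61 were called in every leave-one-out fit, and 399 were lost, by the test or the filter, in at least 1. Over all 27 alternatives 54 were called throughout. Higher genes made up 42.2% of the calls, 61.2% with sex as a covariate, 28.1% without a filter and 23.8% without Rosa26 tumour 3.

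With 1 tumour left out the mitotic list's median ran from -0.267 without translocation tumour 5 to 1.482 without translocation tumour 1. The fibroblast and collagen list's median was -0.041 without translocation tumours 2 and 5 and Rosa26 tumour 4. With sex as a covariate the Y-linked gene Eif2s3y had a log2 fold change of 1.485 in place of -0.19.

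The difference in spread was 24.48 without translocation tumours 2 and 5 and Rosa26 tumour 4 and ran from 33.31 to 70.78 with 1 tumour left out. Against muscle DESeq2 called 5558 genes, the fit without those 3 tumours 7037, and fits with 1 tumour left out 2838 to 5987. No paired analysis was possible because the labels give the genotypes no shared replicate numbers.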

Other observations

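The genes of tumour 5 and the epithelial genes in this part, and the tests of keratinocytes and of transcript length and GC, were chosen only after the result was seen.

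Some transcripts were far higher in translocation tumour 5 than in the other translocation tumours. The melanin enzyme gene Dct was 332 CPM there and at most 0.43 CPM in the other translocation tumours, and up to 27.7 CPM in the Rosa26 tumours. The growth factor gene Fgf15 was 408 CPM against at most 2.05 in any other tumour, and Hoxd13 was 57.5 CPM against at most 0.448. Mitf, the melanocyte regulator, was 180 CPM there and 8.88 to 40.8 CPM in the other translocation tumours. Gpnmb was 529.1 CPM there and 1.413 to 32.33 CPM in the other translocation tumours. Pmel was 0.927 CPM there against 1.49 to 3.65 CPM in the other translocation tumours, and Tyr, Tyrp1 and Mlana had 0 counts there.

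Among epithelial genes picked by eye and not tested as a list, 4 passed as lower in the translocation tumours. The adhesion gene Cdh1 fell by 4.59 on the log2 scale in the translocation tumours (edgeR adjusted p = 0.0321), from 67.4 ± 66.7 CPM (SD, n = 6) to 2.66 ± 3.06 CPM (SD, n = 5). Epcam fell by 5.37 (edgeR adjusted p = 0.0285) and the keratin gene Krt8 by 7.02 (edgeR adjusted p = 0.0133), and Esrp1 had 0 counts in the translocation tumours. Dsg3, at -5.86, and the keratins Krt18 and Krt14, at -2.10 and -1.55, did not pass (edgeR adjusted p = 0.0608, 0.311 and 0.542). Krt5 was at most 0.225 CPM in 4 translocation tumours and 4.94 CPM in tumour 5, and 0 in 5 Rosa26 tumours and 1.47 CPM in tumour 1. Epcam in Rosa26 tumour 4, at 1.14 CPM, lay below translocation tumour 5 at 1.54 CPM.

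Epidermal keratinocytes in the Rosa26 samples could bring such genes, but Krt14 and Krt5 together were 7.87 CPM there against 121 CPM of Dsg3, which speaks against that source. Transcript length and GC could not hold it, since the median of Cdh1, Epcam, Esrp1 and Dsg3 was -5.61 with and without the offset. Other epithelia and an epithelial programme of the tumour cells stay untested.

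Genes within 1 Mb of Ewsr1 or Atf1 might have changed with the translocation. Of 78 tested, 5 passed (6.41%, upper 95% limit 14.3%), against 454 of 16941 elsewhere (2.68%), which leaves the matter undecided (2-sided Fisher's exact test p = 0.0595). The 5 were Uqcr10 (2.43), Cox14 (1.47), Mtfp1 (2.15) and Mrps24 (1.76), which encode mitochondrial proteins, and the neurofilament gene Nefh (-4.91).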
